A study of Mus musculus with 20 samples.

How the data were processed

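Total RNA of whole mouse testis was measured on 20 single-channel 3' expression arrays, 2 for each of 10 days after birth. Per the labels, RNA was extracted with Trizol and labelled with biotin through a one-cycle 3' amplification kit. The deposited table holds 1 intensity per probe set and array on a linear scale, with no detection calls. The software that summarized the probes is not given in the sources used here. The deposited arrays have the same 2% trimmed mean of intensity on all 20 arrays, while other quantiles differ. No further normalization between arrays was applied. 1 array titled as day 18 replicate 2 carries day 0 in another label, and it was analysed under its title.

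Of 45101 probe sets, 64 are controls and were left out of the tests, 13 of them with a gene symbol. Of the others, 34945 carry 1 gene symbol, 932 carry several and 9160 are not listed in the annotation table used for symbols. Symbols were matched by Entrez identifier to a RefSeq gene table of assembly GRCm38.p6 for 34741 of the single-symbol probe sets, for names and chromosomes only. The probe set table names no genome build, so no positions are given. Each of the 18193 genes was represented by its single-symbol probe set with the highest mean log2 intensity. Genes whose probe set exceeded the 40th percentile of its array on at least 2 arrays were tested, 16429 in all. Insl3, Hsd3b6, Hbb-b1 and H19 were on the set of genes to be reported but had no such probe set and are not analysed here. Gapdh has only control probe sets and was not tested. Values were transformed as log2(intensity + 7.83), the added constant being the pooled 20th percentile.

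Differences were tested with limma 3.58.1 in R 4.3.3 (lmFit and eBayes with a trend on mean intensity), with day as a factor of 10 levels fitted to all 20 arrays, 10 residual degrees of freedom and 8.88 prior degrees of freedom. Tests are two-sided. p-values were adjusted by the Benjamini-Hochberg method over the 16429 genes in each comparison, and a gene was called at an adjusted p under 0.05 and a log2 difference of at least 1 in size (2-fold). The time course was tested with the moderated F statistic. There were 5 main comparisons and 9 steps between neighbouring days. Because these share arrays, they are not independent. 25 gene lists (529 genes in all) and the X-linked genes were tested with camera at a preset correlation of 0.01, adjusted over 130 tests, and again with an estimated correlation and with fry. fry asks whether the genes of a list move, on balance, 1 way, and does not compare them with other genes.

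The lists, the model, the thresholds, the main comparisons, the alternatives and the rule for named genes were chosen before the data were examined. By that rule, each main comparison names the 8 largest rises and 8 largest falls among called genes whose arrays of the later day all lay on the same side of those of the earlier day, leaving out symbols of clones, expressed sequences and predicted genes. A list described in full gives the 3 tested members with the largest change in size, leaving out the same kinds of symbols. A fixed set of benchmark genes is given whatever its change. Which lists to describe in full was settled after the results were seen: lists that passed are, and the others are given by their counts, except the adult Leydig cell and steroidogenesis lists on day 35 against day 20, described although they did not pass.

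The model was tested on simulated arrays, drawn at random around the mean of each gene with its residual spread, with known differences added on day 8. Of 50 genes given a log2 difference of 1, 32% were called and 50% passed the adjusted p alone. A call also needs a fitted difference of at least 1, so many genes with a true difference of 1 miss it whatever the precision. For differences of 1.5, 2 and 3 the shares called were 72%, 90% and 100%. Among genes given no difference, of 16429 in all, 3 were called for day 8 against day 0, 2 for day 14 against day 8 and 1 over the time course. Each simulated gene had 1 spread for all days. In the real arrays the median replicate spread ran from 0.0988 on day 6 to 0.182 on day 30. The simulation therefore does not cover errors in comparisons of the later days. Alternatives tried were quantile normalization, a common median, other pseudocounts, other filters, all probe sets or their mean, no trend, array weights, other thresholds, replicate number as a block, fits on the compared days alone and leaving out each array in turn. A floor at the pooled median was added after seeing the data. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15. No array and no column of values was left out.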

Results

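Messenger RNA from whole mouse testis was measured on 20 single-channel oligonucleotide arrays, 2 for each of 10 days after birth from day 0 to day 35. The values are probe set intensities, and each array gave 1 value for each of 45101 probe sets. Whole testis was measured, and all arrays have the same trimmed mean. A fall or rise below therefore cannot be told apart from a change in the share of a cell type in the RNA. Over the 16429 genes tested, the log2 intensities of the 2 arrays of a day correlated across genes with Pearson's r between 0.952 (day 30) and 0.986 (day 6). The first principal component of the 20 arrays carried 75.3% of the variance and the next 9.69%. Array medians ran from 29.4 to 43.4. The number of arrays, 2 a day, limits the precision of every value below. Nothing in the labels says that the replicates came from separate animals, so the p-values measure only the spread between these samples. Where the lower of the 2 day means of a gene lies near or under the constant of 7.83 added before taking logs, the size of its log2 difference depends on that constant. Differences are given on the log2 scale with their standard error (SE), and intensities as mean ± SD, with n = 2 arrays a day throughout. The SE comes from the moderated spread of a gene over all 10 days, not from that of the 2 days compared alone.

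Transcripts of the germ line differed in the day of their highest mean. That day is not the day of first rise: Ldhc went from 18.1 on day 10 to 2176 on day 14. Neighbouring days were also close for some genes, as for Sycp3, with 3417 on day 14 and 3354 on day 20. Stra8, a gene induced by retinoic acid in germ cells before meiosis, rose from 56.4 ± 2.54 on day 0 to 1129 ± 43.1 on day 10 and fell to 126 ± 12.4 on day 35. Kit, the receptor of differentiating spermatogonia, was also highest on day 10, at 321 ± 1.86. Dnmt3l, a cofactor of DNA methylation in fetal male germ cells, had 86.9 ± 11.4 on day 0 and 4.70 ± 1.60 on day 3. Sycp3, a component of the synaptonemal complex, was highest on day 18 at 3542 ± 190. Spo11, which makes the DNA breaks of meiotic recombination, was highest on day 20 at 968 ± 8.96. Piwil1, a partner of pachytene piRNAs, was highest on day 18 at 1530 ± 51.0, and Hspa2, a chaperone of spermatocytes, on day 30 at 2192 ± 272. Ldhc and Pgk2, which encode glycolytic enzymes of germ cells, reached 8853 ± 7.04 on day 30 and 3835 ± 38.9 on day 35. Acrv1, an acrosomal protein, and Odf1, a protein of the sperm tail, were highest on day 35 at 1868 ± 84.6 and 5770 ± 449. The transition protein genes Tnp1 and Tnp2 and the protamine genes Prm1 and Prm2 had mean intensities of at most 61.0 (Prm2 on day 20) up to day 20 and were highest on day 30, at 9678 ± 363, 8511 ± 50.8, 9494 ± 6.71 and 11550 ± 58.0.

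Several somatic transcripts followed other courses. Amh, the Sertoli cell hormone that removes the Müllerian duct, was highest on day 3 at 761 ± 187 and had 10.2 ± 2.34 on day 35. Cyp17a1, an enzyme of androgen synthesis, had 1752 ± 67.1 on day 0, 426 ± 42.7 on day 6 and 2424 ± 57.3 on day 30. Hsd17b3, which makes testosterone, had 1279 ± 51.8 on day 0, 87.0 ± 12.3 on day 14 and 353 ± 6.35 on day 35. Star, which carries cholesterol into mitochondria, was highest on day 0 at 367 ± 1.25 and lowest on day 6 at 146 ± 0.830. Cyp26b1, which degrades retinoic acid, was highest on day 14 at 689 ± 78.8. Col1a1, a chain of type I collagen, was highest on day 3 at 3282 ± 271, and Igf2, an imprinted growth factor, also on day 3 at 2721 ± 44.9. Mki67, a marker of dividing cells, was highest on day 0 at 1617 ± 7.98 and lowest on day 35 at 177 ± 19.4. Hba-a1, a chain of haemoglobin, stayed between 0.583 ± 0.0110 on day 10 and 42.0 ± 39.3 on day 30. Bacterial control probe sets had medians of 1.61 on days 0 to 14 and 8.09 on days 18 to 35. Those for 1 bacterial transcript reached 44.1 on 1 later array. The Hba-a1 probe set thus lay near the level of controls, and no course of haemoglobin RNA is read from it. Of the 16429 genes, 12748 (77.6%) passed the time course test (moderated F test, adjusted p under 0.05, and day means at least 2-fold apart). The range of day means exceeded 4-fold for 6721 of them and 16-fold for 1334. The highest mean fell on days 0 to 10 for 5659 of the 12748 genes, on days 14 to 20 for 2610 and on days 30 or 35 for 4479. The time course spans a step in the lowest values of the arrays between days 14 and 18, described below, so part of these counts may rest on it.

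**Figure D1:**
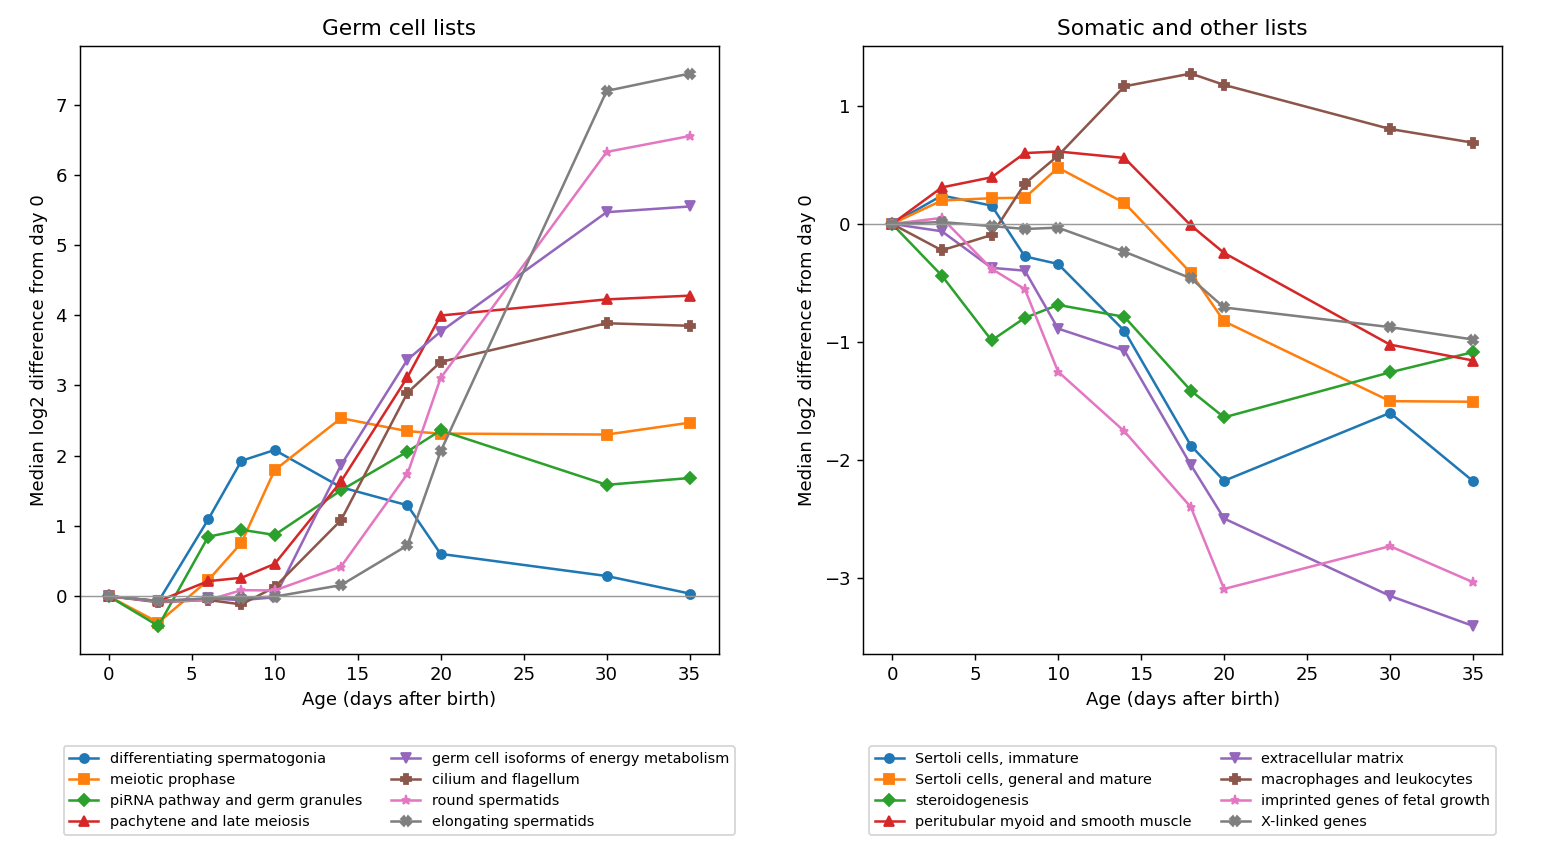
Median log2 difference from day 0 of the members of each gene list (vertical axis) by day after birth (horizontal axis), each value from the means of 2 arrays a day. The differentiating spermatogonia list was highest on day 10 at 2.08, the meiotic prophase list on day 14 at 2.53, and the round and elongating spermatid lists on day 35 at 6.55 and 7.44, where the extracellular matrix list stood at −3.40.

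**Figure D2:**
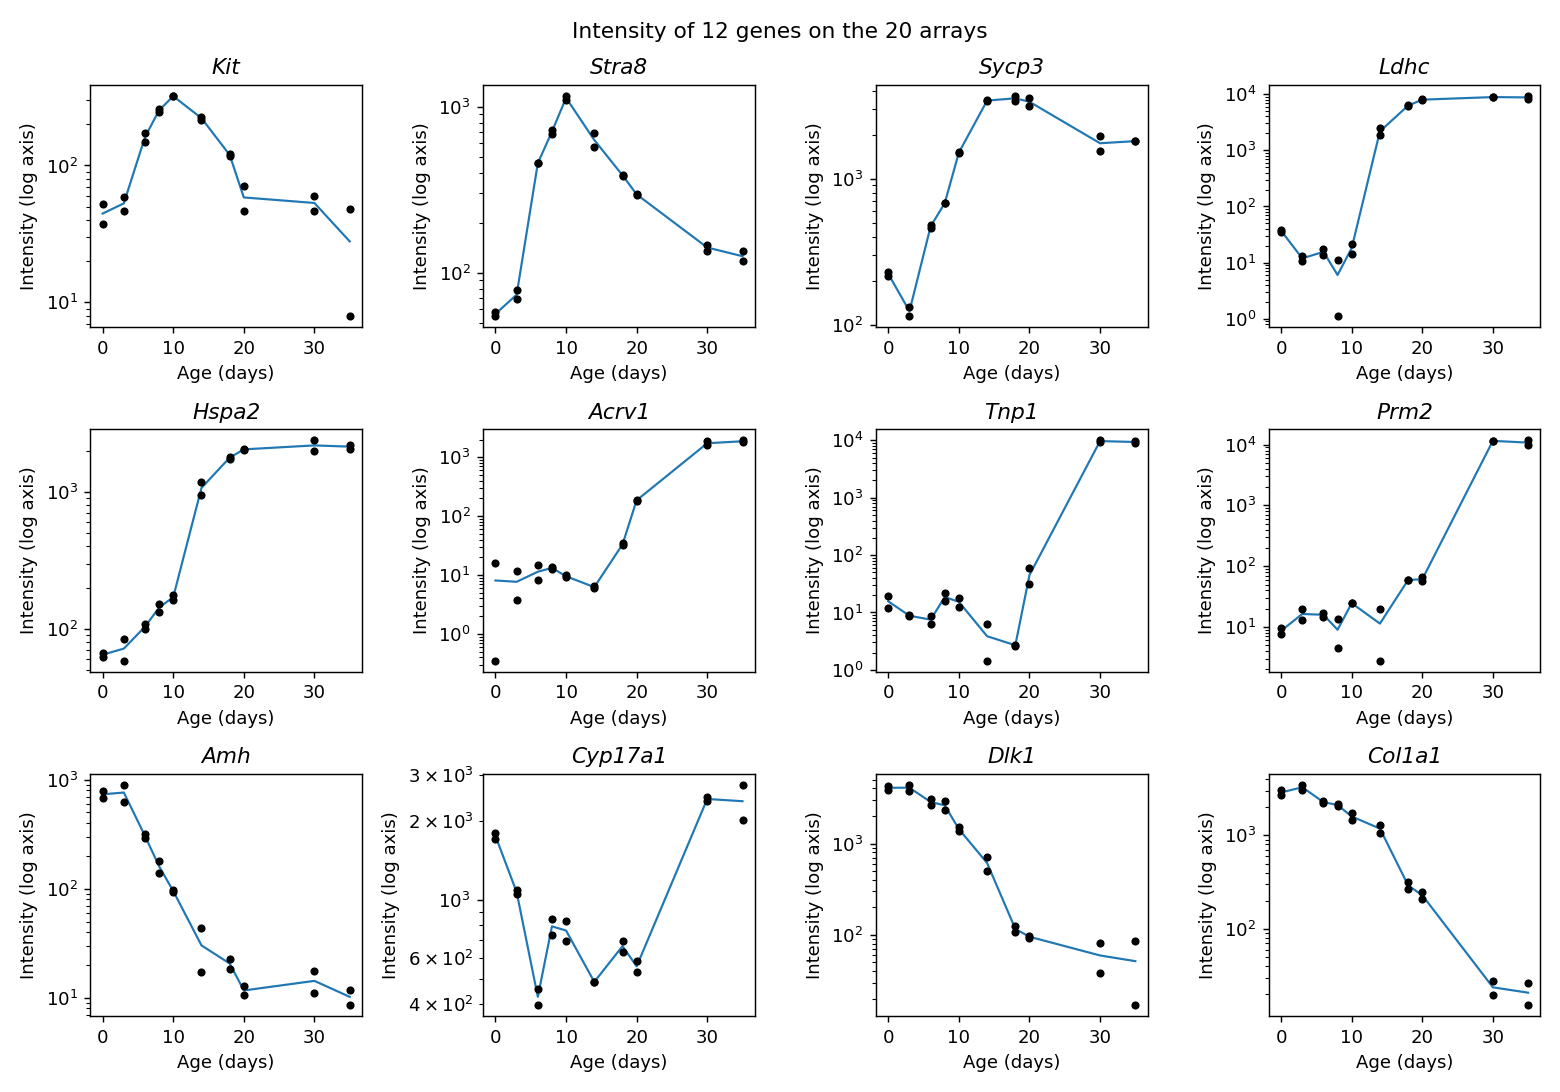
Intensity of single genes on each array (points, log axis) and the mean of the 2 arrays of a day (lines) by day after birth. Kit and Stra8 were highest on day 10 and Sycp3 on day 18, while Prm2 rose from 61.0 on day 20 to 11550 on day 30.

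Day 8 was set against day 0 to describe the interval from birth to the end of the period in which the tubules hold spermatogonia and dividing Sertoli cells. Stra8 rose by 3.47 ± 0.11 (SE), from 56.4 to 706, and Neurog3, a gene of undifferentiated spermatogonia, by 3.61 ± 0.44, from 2.45 to 116. The other 6 of the 8 largest rises were those of the lysophosphatidic acid receptor Lpar3 (3.62 ± 0.20), the epididymal protease inhibitor Eppin (3.32 ± 0.12), Bard1, the partner of Brca1 (3.29 ± 0.29), cardiac troponin T, Tnnt2 (3.17 ± 0.20), the retinoic acid-binding protein Crabp1 (3.06 ± 0.22) and Cbr2 (3.03 ± 0.28). Ccl17, a chemokine, fell by 5.32 ± 0.34 on the log2 scale, from 941 ± 302 to 15.4 ± 2.66. Cbln1 fell by 3.85 ± 0.38, Npy, neuropeptide Y, fell by 3.58 ± 0.42, Ptgds, prostaglandin D synthase, fell by 3.54 ± 0.18, and Pnmt, which makes adrenaline, fell by 3.51 ± 0.35. Miox fell by 3.48 ± 0.39, S100a8, a protein of neutrophils, fell by 3.19 ± 0.75, and the ion channel gene Cnga1 fell by 3.02 ± 0.34. Dnmt3l fell by 1.77 ± 0.36.

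Of 15 tested genes of differentiating spermatogonia, 13 rose, 1 fell and 1 did not pass (camera adjusted p = 9.39e-17). Stra8, Dmrtb1 (2.86 ± 0.21), a regulator of the switch from mitosis to meiosis, and Kit (2.33 ± 0.36) led them. Of 34 meiotic prophase genes 16 rose and none fell (adjusted p = 2.02e-12), with Tex11 (2.45 ± 0.18), Syce1 (1.96 ± 0.10) and the meiotic cohesin Rec8 (1.95 ± 0.31) as the largest. The piRNA pathway list had 8 of 17 members higher and none lower (adjusted p = 1.93e-13), led by the Tudor domain genes Rnf17 (2.02 ± 0.12, and 0.02 in another probe set) and Tdrd1 (1.72 ± 0.27) and the helicase Mov10l1 (1.69 ± 0.12). In the pachytene list 7 of 31 genes rose, 8 adjusted over the list alone (adjusted p = 0.00213), with Taf7l at 2.50 ± 0.13, Meig1 at 2.25 ± 0.14 and the X-linked Nxf2 at 1.63 ± 0.11. These 4 lists also passed with an estimated correlation (the highest adjusted p was 0.0308). Among 23 genes of prospermatogonia and undifferentiated spermatogonia 6 rose, 1 fell and 16 did not pass (adjusted p = 0.0214). Neurog3, Sox3 (2.97 ± 0.20) and the RNA-binding Lin28a (2.42 ± 0.21) had the largest changes there, and the list had an adjusted p = 0.255 with an estimated correlation.

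Somatic lists went both ways between these days. Peritubular myoid genes had 4 of 12 members higher and none lower (adjusted p = 7.85e-07, and adjusted p = 0.0141 with an estimated correlation), led by the smooth muscle genes Cnn1 (2.10 ± 0.28), Myh11 (1.76 ± 0.16) and Lmod1 (1.38 ± 0.34). Steroidogenic genes fell, 4 of 10 lower and none higher (adjusted p = 2.15e-08, and adjusted p = 0.0530 with an estimated correlation), with the side-chain cleavage enzyme Cyp11a1 at −1.79 ± 0.15, Hsd17b3 at −1.74 ± 0.13 and Cyp17a1 at −1.14 ± 0.12. The adult Leydig cell list had 2 of 11 higher and 2 lower (camera direction down, adjusted p = 0.0272, and adjusted p = 0.190 with an estimated correlation). Ptgds, Vcam1 (2.07 ± 0.19) and Hsd11b1 (1.31 ± 0.45) were its largest changes. General and mature Sertoli cell genes had 4 of 21 higher and 1 lower (adjusted p = 0.00807, and adjusted p = 0.0814 with an estimated correlation), led by the tight junction gene Cldn11 (3.02 ± 0.13), the transcription factor Gata1 (2.04 ± 0.18) and Cldn3 (1.61 ± 0.43). Extracellular matrix genes had 2 of 24 lower and none higher (adjusted p = 2.74e-06, and adjusted p = 0.0708 with an estimated correlation), with Fbln1 at −1.14 ± 0.21 and Lum at −1.03 ± 0.22, while Postn, at 0.95 ± 0.15, did not pass. Of 15 imprinted genes of fetal growth 3 were lower and 1 higher (adjusted p = 2.16e-05, and adjusted p = 0.0838 with an estimated correlation), with Mest at −1.65 ± 0.18, Phlda2 at 1.65 ± 0.44 and Slc38a4 at −1.49 ± 0.43. Of 14 endothelial genes 1 was lower, 2 adjusted over the list alone (adjusted p = 0.00338, and adjusted p = 0.0550 with an estimated correlation): Vwf, von Willebrand factor, stood at −1.37 ± 0.35, and Tie1 (−1.18 ± 0.45) and Tek (from 89.3 ± 6.02 to 41.2 ± 9.71 in intensity) did not pass.

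The remaining lists did not pass between days 0 and 8. Immature Sertoli cell genes had 2 of 13 higher and 5 lower (adjusted p = 0.286), and their median of −0.28 became 0.39 among the members above the median level. Amh fell by 2.15 ± 0.28 in this list. Retinoid genes had 2 of 18 higher and 1 lower (adjusted p = 0.278), erythroid genes 2 of 5 lower (0.114), and macrophage and leukocyte genes 2 of 19 higher and 2 lower (0.109). Round spermatid genes had 1 of 34 higher and 2 lower, 1 and 1 adjusted over the list alone (0.400), and elongating spermatid genes 1 of 33 higher and 1 lower, 0 and 0 adjusted over the list alone (0.603). The germ cell isoforms of energy metabolism had 4 of 17 higher and 1 lower (0.845), their somatic counterparts 1 of 14 higher (0.102), and X-linked genes 49 of 559 higher, 50 adjusted over the list alone, and 16 lower (0.859). No member of the cell cycle (0.246), cholesterol synthesis (0.238), cilium (0.356), epididymis (0.964) or adipose and skeletal muscle (0.0997) lists passed. Median and mean differed in sign for the X-linked genes (−0.04 and 0.06), the germ cell isoforms of energy metabolism (−0.06 and 0.05) and the cell cycle list (0.01 and −0.07), and camera took the sign of the mean in each. In all, 540 genes rose and 455 fell, and the second count was 294 without day 0 replicate 2 and 283 with a pseudocount at the 40th percentile. Which direction held more genes rests on the scaling: with each array set to a common median 493 rose and 510 fell (49.2% higher), and under quantile normalization 491 and 346.

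Single arrays decided some of these calls. Without day 0 replicate 1 the calls of S100a8 (−2.85), Slc38a4 (−1.29), Phlda2 (0.87) and Hsd11b1 (0.91) ended, and without day 0 replicate 2 those of Lmod1 (0.86), Lum (−0.97), Vwf (−1.24) and Cldn3 (1.26). Without day 8 replicate 1 those of Slc38a4 (−1.59), Phlda2 (1.71), Hsd11b1 (1.28), Lum (−0.97), Vwf (−1.35) and Cldn3 (1.26) ended, and without day 8 replicate 2 those of S100a8 (−1.74), Slc38a4 (−1.38), Phlda2 (1.59), Hsd11b1 (1.35), Lmod1 (1.19) and Fbln1 (−0.93). The call of Hsd11b1 also ended, at an unchanged 1.31, without any 1 of the 2 arrays of day 6 or of day 14. Averaging all probe sets of a gene ended the calls of Cyp11a1 (−0.49) and Fbln1 (−0.99). With values floored at the pooled median, a setting chosen after seeing the data, those of Rec8 (0.68), Lmod1 (0.79), Phlda2 (0.59), Cldn3 (0.22) and Hsd11b1 (0.40) ended, and with a pseudocount at the 40th percentile those of Lum (−0.98) and Hsd11b1 (0.92). A pseudocount at the 5th percentile ended the calls of Slc38a4 (−1.61) and Hsd11b1 (1.66), quantile normalization and a fit without a trend that of Hsd11b1 (1.28 and 1.31), and an adjusted p under 0.01 those of Slc38a4, Phlda2, Cldn3 and Hsd11b1. The calls of other genes held with values moved over 1.5 times: averaged probe sets gave Tnnt2 1.83, Myh11 1.10 and Cldn3 1.03, and the floor gave Lpar3 1.90, Neurog3 1.75, Bard1 1.49, Cbr2 1.46, Npy −2.33, Cnga1 −1.02 and Meig1 1.22, while Cnga1 stood at −1.97 with a pseudocount at the 40th percentile. Tek was called with a common median (−1.04), a pseudocount at the 5th percentile (−1.10), the floor (−1.13) and without replicate 1 of day 0 (−1.06) or of day 8 (−1.20), and Postn without day 0 replicate 2 (1.08). Tie1 was called, at an unchanged −1.18, with array weights, in a fit on the compared days alone and without either array of day 35. Other probe sets of Tnnt2 (−0.40) and Cyp11a1 (0.63) pointed the other way and were not called.

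Day 14 was set against day 8 to describe the entry of germ cells into meiosis. Ldhc, the lactate dehydrogenase of germ cells, rose by 7.38 ± 0.22, from 6.04 ± 6.96 to 2176 ± 445. The next largest rises were those of Spata4 (6.96 ± 0.22), Pdcl2 (6.21 ± 0.21), Fabp9, a fatty acid-binding protein of the sperm head (6.10 ± 0.21), Ldhal6b (5.82 ± 0.15), the ceramide synthase Cers3 (5.19 ± 0.22), Mroh4 (5.14 ± 0.22) and the glycerol kinase Gk2 (5.06 ± 0.16). This order rests on the added constant: with a pseudocount at the 5th percentile Spata4 stood at 8.67 and Ldhc at 8.53. The defensin gene Defb42 fell by 3.42 ± 0.34, Hsd17b1, which reduces estrone to estradiol, fell by 3.23 ± 0.33, and H3f3b fell by 3.03 ± 0.28. The glutamate transporter Slc1a6 fell by 2.81 ± 0.27, Sel1l3 fell by 2.77 ± 0.26, the angiotensin receptor Agtr2 fell by 2.75 ± 0.33, Lpcat2 fell by 2.66 ± 0.31 and S100a8 fell by 2.56 ± 0.75. Kit (−0.19 ± 0.36) and Stra8 (−0.17 ± 0.11) did not pass between these days.

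Of 34 meiotic prophase genes 24 rose and none fell (adjusted p = 3.10e-23), with Meiob, which coats single-stranded DNA in meiosis, at 5.02 ± 0.27, Hormad1 at 3.83 ± 0.33 and Spo11 at 3.37 ± 0.20. Sycp3 rose by 2.31 ± 0.10. Pachytene genes had 17 of 31 higher and 1 lower (adjusted p = 1.34e-15), led by Adam2 (4.92 ± 0.34), Meig1 (4.44 ± 0.14) and Ybx2 (4.05 ± 0.12), an RNA-binding protein of germ cells, and including Piwil1 (3.83 ± 0.17) and Hspa2 (2.83 ± 0.14). Of 34 round spermatid genes 12 rose (adjusted p = 2.90e-05), with Gk2, Crisp2 (4.63 ± 0.28) and Dkkl1 (4.46 ± 0.41) first. The germ cell isoforms of energy metabolism had 8 of 17 higher (adjusted p = 1.16e-09): Ldhc, Ldhal6b and the pyruvate dehydrogenase subunit Pdha2 (4.47 ± 0.18) led them. Pgk2 stood at 1.67 ± 0.33, and its call ended with a pseudocount at the 40th percentile (0.97) and with the floor at the pooled median (0). Cilium and flagellum genes had 11 of 21 higher (adjusted p = 1.62e-11), led by the radial spoke gene Rsph1 (5.03 ± 0.12), Ccdc39 (3.90 ± 0.13) and the dynein Dnah8 (3.85 ± 0.13). None of the members of these 3 last lists fell, and all 5 lists passed with an estimated correlation (the highest adjusted p was 0.0141). The piRNA pathway list rose as a set (adjusted p = 1.11e-06, and adjusted p = 0.0530 with an estimated correlation), although only Tdrd9 (1.10 ± 0.15) of its 17 members passed, and Gpat2 (0.98 ± 0.13) and Mov10l1 (0.95 ± 0.12) did not. Both were called under quantile normalization (1.05 and 1.04) and without day 14 replicate 2 (1.09 and 1.12), Mov10l1 also without day 8 replicate 1 (1.01) and Gpat2 also with the floor.

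Macrophage and leukocyte genes had 7 of 19 higher and none lower (adjusted p = 7.42e-07, and adjusted p = 0.0357 with an estimated correlation), with lysozyme, Lyz2, at 1.37 ± 0.16, Cd14 at 1.36 ± 0.37 and H2-Ab1 at 1.31 ± 0.40. Immature Sertoli cell genes had 4 of 13 lower and none higher (adjusted p = 7.63e-04, and adjusted p = 0.0152 with an estimated correlation), led by Hsd17b1, Amh (−2.23 ± 0.28) and Bex2 (−1.49 ± 0.11). Extracellular matrix genes had 7 of 24 lower (adjusted p = 6.69e-13, and adjusted p = 0.0135 with an estimated correlation), with Fbln2 at −2.41 ± 0.38, Postn at −2.06 ± 0.15 and fibronectin, Fn1, lower at 404 ± 0.952 from 1157 ± 49.8 in intensity. Of 15 imprinted genes 7 fell, 8 adjusted over the list alone (adjusted p = 2.68e-10, and adjusted p = 0.0193 with an estimated correlation), with Dlk1 at −2.10 ± 0.37, the noncoding Meg3 at −1.90 ± 0.14 and Mest at −1.77 ± 0.18, and Igf2 at −1.28 ± 0.15. Cholesterol synthesis genes fell as a set (adjusted p = 8.61e-05, and adjusted p = 0.0482 with an estimated correlation), but none of the 14 passed alone: Mvd stood at −0.84 ± 0.27, Fdps at −0.78 ± 0.09 and Fdft1 at −0.68 ± 0.10. Of 23 genes of prospermatogonia and undifferentiated spermatogonia 4 fell, 5 adjusted over the list alone, and 1 rose (adjusted p = 0.0120, and adjusted p = 0.217 with an estimated correlation): Id4 stood at 2.22 ± 0.11, Neurog3 at −1.67 ± 0.44 and Upp1 at −1.53 ± 0.32.

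Weaker sets and lists that did not pass complete this interval. Cell cycle genes had 2 of 26 higher and 1 lower (camera direction down, adjusted p = 0.0142, and adjusted p = 0.217 with an estimated correlation), with Ccne2 at 1.28 ± 0.16, Aurkb at −1.11 ± 0.19 and Bub1 at 1.02 ± 0.09. X-linked genes had 27 of 559 higher and 18 lower (camera direction down, adjusted p = 0.0126, and adjusted p = 0.0598 with an estimated correlation), with Tsx at 4.46 ± 0.13, Agtr2, and the RNA export gene Nxf3 at 2.69 ± 0.17. Elongating spermatid genes had 5 of 33 higher and 1 lower (adjusted p = 0.0953), differentiating spermatogonia 1 of 15 higher and 2 lower (0.718), and general Sertoli cell genes 2 of 21 higher and 3 lower (0.347). The last had a median of −0.18 and a mean of 0.08, differentiating spermatogonia −0.10 and 0.04, both with camera direction down, and the epididymal list −0.02 and 0.10, with camera direction up. Retinoid genes had 3 of 18 higher, 4 adjusted over the list alone (0.526), and adipose and skeletal muscle genes 1 of 12 higher, 0 adjusted over the list alone (0.748). Steroidogenic genes had 1 of 10 higher and 1 lower (0.950), among them Hsd17b3 at −2.03 ± 0.13, and adult Leydig cell genes 1 of 11 higher and 1 lower (0.814). No member of the somatic energy metabolism (0.0717), myoid (0.353), endothelial (0.0997), erythroid (0.648) or epididymal (0.979) lists passed. In all, 900 genes rose and 410 fell, and the second count was 247 with a pseudocount at the 40th percentile.

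Without day 8 replicate 1 the calls of S100a8 (−1.11) and H2-Ab1 (1.33) ended, and without day 8 replicate 2 those of H2-Ab1 (1.29) and Cd14 (1.24). Without day 14 replicate 1 those of S100a8 (−1.55), H2-Ab1 (1.21), Aurkb (−0.96), Bub1 (0.96) and Tdrd9 (0.91) ended, and without day 14 replicate 2 those of Neurog3 (−1.54), H2-Ab1 (1.42) and Cd14 (1.24). Averaging all probe sets ended the calls of Meg3 (−0.80), Aurkb (−0.99) and Bub1 (0.68). Quantile normalization ended that of H2-Ab1 (1.12), a pseudocount at the 40th percentile that of Cd14 (0.97), and the floor those of Cd14 (0.47) and S100a8 (−1.47). The call of S100a8 also ended, at an unchanged −2.56, in a fit without a trend, in a fit on the compared days alone and at an adjusted p under 0.01, and without day 8 replicate 2 it stood at −4.02. That of H2-Ab1 also ended with a pseudocount at the 5th percentile and at an adjusted p under 0.01, and that of Aurkb (−0.86) when probe sets prone to cross-hybridization were left out. Averaged probe sets kept the calls of Sel1l3 (−1.54), Lpcat2 (−1.59), Ccdc39 (1.86), Dnah8 (1.94), Fbln2 (−1.44) and Dlk1 (−1.20) at values moved over 1.5 times, and the floor those of Ldhal6b (3.86), Mroh4 (3.23) and Defb42 (−1.94). Of the other probe sets of Meg3, 4 pointed the other way (0.01 to 0.26) and were not called.

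Day 20 was set against day 14 to describe late meiotic prophase up to the first round spermatids. Hspb9, a small heat shock protein of the testis, rose by 6.34 ± 0.29, from 33.0 ± 7.28 to 3279 ± 293. The next largest rises were those of Ms4a19 (6.18 ± 0.29), Tmed6 (6.09 ± 0.30), Toporsl (5.64 ± 0.28), Cmtm2b (5.56 ± 0.23), the serine protease Prss39 (5.49 ± 0.40), the sperm surface protein Adam3 (5.40 ± 0.20) and Tmem225 (5.34 ± 0.31). Their order rests on the added constant: with a pseudocount at the 5th percentile Tmed6 stood at 7.75, Ms4a19 at 7.13 and Hspb9 at 6.58. The elastic fibre gene Mfap4 fell by 3.61 ± 0.21, Ldb1 fell by 2.94 ± 0.41, the orphan receptor Nr4a1 fell by 2.75 ± 0.15 and Aplf, of DNA end joining, fell by 2.70 ± 0.38. The imprinted Plagl1 fell by 2.68 ± 0.11, the receptor Met fell by 2.66 ± 0.28, endoglin, Eng, fell by 2.60 ± 0.31 and Emp2 fell by 2.59 ± 0.28. Kit fell by 1.82 ± 0.36 and Stra8 fell by 1.06 ± 0.11, while Spo11 rose by 1.57 ± 0.20 and Piwil1 by 1.54 ± 0.17. Hspa2, at 0.94 ± 0.14, did not pass, but did without day 14 replicate 1 (1.10).

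Spermatid genes were mostly higher on day 20. Of 34 round spermatid genes 26 rose, 27 adjusted over the list alone, and none fell (adjusted p = 4.08e-11), with Pgam2 at 4.76 ± 0.16, Tekt4 at 4.04 ± 0.47 and Zpbp2 at 3.99 ± 0.30, and Acrv1 at 3.78 ± 0.36. Elongating spermatid genes had 25 of 33 higher and none lower (adjusted p = 5.00e-09), led by Smcp (4.88 ± 0.36), the spermatid linker histone Hils1 (3.68 ± 0.24) and Tcp11 (3.57 ± 0.28), and Tnp1 rose by 2.15 ± 0.28, to 44.7 ± 19.5, and Prm2 from 11.4 ± 12.1 to 61.0 ± 6.94. Pachytene genes had 17 of 31 higher and 2 lower (adjusted p = 4.86e-08), with the male germ cell cyclin Ccna1 at 5.19 ± 0.35, Spata16 at 3.79 ± 0.25 and Papolb at 3.78 ± 0.22. Cilium and flagellum genes had 18 of 21 higher (adjusted p = 6.15e-11), with the dynein gene Dnaic2 at 4.61 ± 0.28, Tekt2 at 3.39 ± 0.19 and Spag16 at 3.37 ± 0.24. The germ cell isoforms of energy metabolism had 16 of 17 higher (adjusted p = 4.80e-09): Pgk2 rose by 4.89 ± 0.33, the monocarboxylate transporter Slc16a7 by 3.36 ± 0.25 and Ldhal6b by 2.91 ± 0.15, and Ldhc rose by 1.88 ± 0.22. All 5 lists passed with an estimated correlation (the highest adjusted p was 0.0155). Their somatic counterparts had 1 of 14 higher and 6 lower (adjusted p = 6.64e-05, and adjusted p = 0.0693 with an estimated correlation), with Ldha at 2.04 ± 0.09, Slc16a1 at −1.45 ± 0.16 and the phosphofructokinase Pfkl at −1.38 ± 0.12.

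Genes of the X chromosome were lower more often than those of any autosome. Of 559 tested X-linked genes 173 fell and 53 rose, 54 adjusted over the list alone (adjusted p = 4.84e-09, and adjusted p = 9.51e-04 with an estimated correlation). The X-linked median was −0.72, against medians between −0.04 and 0.09 on the 19 autosomes, and under quantile normalization it lay 0.64 below the autosomal median (difference −0.64). The largest changes were rises, of the spermatid genes Tsga8 (4.96 ± 0.33), Cypt1 (3.19 ± 0.34) and Akap4, a scaffold of the fibrous sheath (2.99 ± 0.37).

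**Figure D3:**
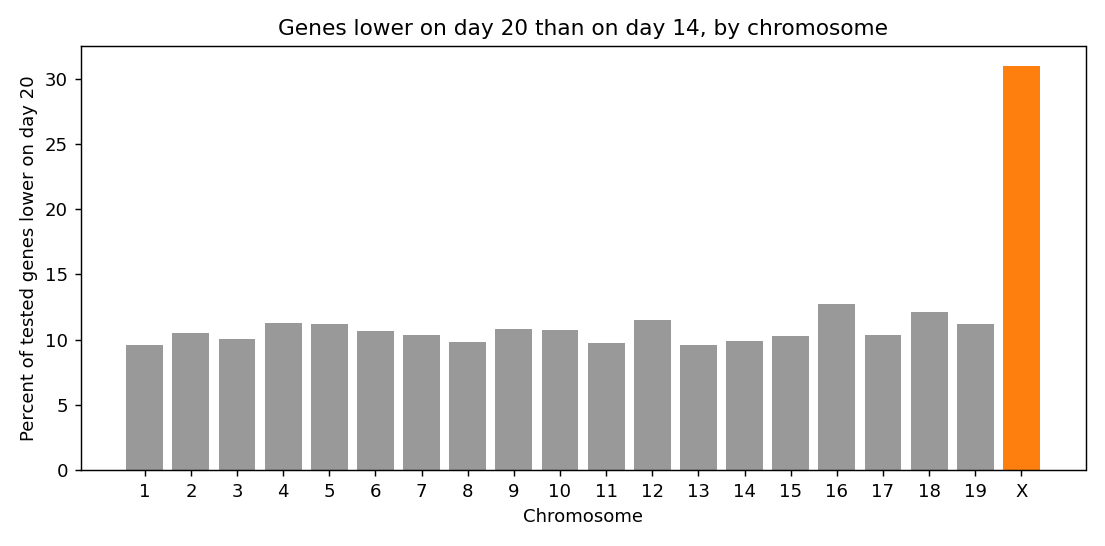
Percent of the tested genes of each chromosome that were called lower on day 20 than on day 14 (limma, adjusted p under 0.05 and at least 2-fold), from 2 arrays a day. The X chromosome, with 173 of 559 genes lower, stands above every autosome.

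Extracellular matrix genes had 18 of 24 lower and 1 higher (adjusted p = 6.64e-10, and adjusted p = 0.0249 with an estimated correlation), led by Mfap4 and the type I collagen genes Col1a1 (−2.33 ± 0.16, and −0.89 in another probe set) and Col1a2 (−1.97 ± 0.13). General Sertoli cell genes had 8 of 21 lower (adjusted p = 7.72e-05, and adjusted p = 0.0190 with an estimated correlation), with the spermatogonial growth factor Gdnf at −1.89 ± 0.26, Dmrt1 at −1.59 ± 0.11 and desert hedgehog, Dhh, at −1.39 ± 0.10. Immature Sertoli cell genes had 5 of 13 lower and 1 higher (adjusted p = 0.00442, and adjusted p = 0.0302 with an estimated correlation), with the inhibin subunit Inhbb at −1.33 ± 0.09, Krt8 at 1.25 ± 0.24 and Bex2 at −1.22 ± 0.11. Imprinted genes had 9 of 15 lower (adjusted p = 1.57e-04, and adjusted p = 0.117 with an estimated correlation), with Plagl1, Dlk1 (−2.56 ± 0.37) and Igf2 (−1.53 ± 0.15) first. Peritubular myoid genes had 4 of 12 lower (adjusted p = 7.63e-04, and adjusted p = 0.0621 with an estimated correlation), with Myh11 at −1.79 ± 0.16, Mylk at −1.14 ± 0.08 and Tpm2 at −1.10 ± 0.15. Differentiating spermatogonia had 8 of 15 lower and 1 higher (adjusted p = 0.00651, and adjusted p = 0.0857 with an estimated correlation): Dmrtb1 stood at 3.18 ± 0.21, Kit at −1.82 ± 0.36 and the cyclin Ccnd2 at −1.61 ± 0.10.

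The other lists did not pass: undifferentiated spermatogonia 7 of 23 lower (adjusted p = 0.221), meiotic prophase 4 of 34 higher and 9 lower (0.604), and the piRNA pathway 5 of 17 higher and 1 lower (0.0525). Retinoid genes had 2 of 18 higher and 5 lower (0.241), cell cycle genes 4 of 26 higher and 7 lower (0.312), cholesterol synthesis genes 1 of 14 higher and 2 lower (0.174) and steroidogenic genes 1 of 10 lower (0.258). Adult Leydig cell genes had 2 of 11 lower (0.388), endothelial genes 2 of 14 lower (0.344), macrophage and leukocyte genes 2 of 19 higher (0.718), epididymal genes 1 of 6 higher (0.388), adipose and skeletal muscle genes 4 of 12 higher and 1 lower (0.469), and erythroid genes 0 of 5 (0.748). In all, 2990 genes rose and 1845 fell.

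This comparison crosses a step in the lowest values of the arrays. The 27 bacterial control probe sets that are not hybridization controls had a median of 1.61 over the 12 arrays of days 0 to 14 and 8.09 over the 8 arrays of days 18 to 35, so the step and the change of day cannot be told apart here. The difference between 3' and 5' control probe sets of Actb, a sign of RNA quality, was 0.655 to 0.978 on days 0 to 14, 1.07 to 1.18 on days 18 to 30 and 0.878 to 0.953 on day 35. The same difference for Gapdh was −0.415 and −0.394 on day 14 and −0.357 and −0.215 on day 20. Over days 0 to 14 the Gapdh difference ran from −0.418 to −0.175, which covers the values of day 20. With values floored at the pooled median, a setting chosen after seeing the data, 1782 genes rose, and the calls of Tnp1 (0.38), Prm2 (0.82), Akap4 (0.94), Met (−0.94), Gdnf (−0.49) and Krt8 (0.65) ended. A pseudocount at the 40th percentile ended the call of Krt8 (0.92). Without day 14 replicate 1 the call of Stra8 (−0.92) ended, without day 14 replicate 2 that of Krt8 (0.91), and without day 20 replicate 1 that of Tpm2 (−0.99). Averaging all probe sets ended the calls of Igf2 (−0.13), which has another probe set that rose by 1.27, Pfkl (−0.51), Myh11 (−0.92) and Tpm2 (−0.51). It kept those of Aplf (−1.29), Plagl1 (−1.36), Met (−1.56), Emp2 (−1.13), Zpbp2 (2.30), Dnaic2 (2.73), Col1a2 (−1.18), Dlk1 (−1.38) and Spag16 (1.32) at values moved over 1.5 times. The floor did so for Tmem225 (3.47), Aplf (−1.20), Acrv1 (2.43), Smcp (3.14), Hils1 (1.73), Dnaic2 (2.75) and Cypt1 (1.01), and leaving out day 14 replicate 2 for Prm2 (1.30) and probe sets prone to cross-hybridization for Plagl1 (−1.02). With a pseudocount at the 40th percentile Tnp1 stood at 1.35, Akap4 at 1.99 and Cypt1 at 2.04. Other probe sets of Aplf (0.12), Col1a2 (0.11) and Tpm2 (0.94) pointed the other way, as did 1 of Pfkl, and those of Emp2 (−0.26 and −0.55) and Met (−0.46) were lower, none of them called.

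Day 35 was set against day 20 to describe the differentiation of spermatids up to the end of the first wave of spermatogenesis. Tnp2 rose by 9.31 ± 0.29, from 4.93 ± 2.02 to 8032 ± 371, Prm1 by 8.00 ± 0.42, Tnp1 by 7.52 ± 0.28 and Prm2 by 7.29 ± 0.32. The spermatid histone genes H2al2a (7.64 ± 0.38) and H2bl1 (7.37 ± 0.40) rose with them, as did Asb17 (7.69 ± 0.36) and Cby2 (7.63 ± 0.28). Col1a1 fell by 3.08 ± 0.16, from 229 ± 27.3 to 20.7 ± 7.77, and Nsd3, a histone methyltransferase, fell by 2.75 ± 0.32. Blvrb fell by 2.33 ± 0.34, Map3k2 fell by 2.31 ± 0.24, Fam50a fell by 2.30 ± 0.18, Antxr1 fell by 2.27 ± 0.28, Prss35 fell by 2.27 ± 0.11 and Mtcp1 fell by 2.26 ± 0.19. Cyp17a1 rose by 2.06 ± 0.12, from 557 ± 39.6 to 2377 ± 516, and Hsd17b3 by 1.70 ± 0.13.

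Elongating spermatid genes had 28 of 33 higher and none lower (adjusted p = 1.49e-27), led by Tnp2, Prm1 and Tnp1, and Odf1 rose by 5.24 ± 0.33. Round spermatid genes had 23 of 34 higher and none lower (adjusted p = 1.61e-19), with Txndc2 at 7.22 ± 0.41 and the testis kinases Tssk2 at 5.64 ± 0.28 and Tssk3 at 5.41 ± 0.41, and Acrv1 at 3.28 ± 0.36. The germ cell isoforms of energy metabolism had 7 of 17 higher (adjusted p = 6.64e-05), with Gapdhs at 5.32 ± 0.20, Aldoart1 at 4.77 ± 0.34 and the sodium pump Atp1a4 at 4.10 ± 0.40, and Pgk2 at 1.89 ± 0.33. These 3 lists passed with an estimated correlation (the highest adjusted p was 0.00848). Their somatic counterparts had 1 of 14 higher and 1 lower (camera direction down, adjusted p = 0.00565, and adjusted p = 0.176 with an estimated correlation), with Pgk1 at −1.23 ± 0.12 and Aldoa at 1.12 ± 0.09, while Slc2a1 (−0.91 ± 0.12) did not pass. Differentiating spermatogonia had 3 of 15 lower (adjusted p = 0.00442, and adjusted p = 0.0788 with an estimated correlation), with Prss50 at −1.70 ± 0.26, Stra8 at −1.19 ± 0.11 and Kit at −1.14 ± 0.36. Cell cycle genes had 1 of 26 lower (adjusted p = 0.00442, and adjusted p = 0.157 with an estimated correlation): Mcm2 stood at −1.20 ± 0.18, and Gmnn (−0.98 ± 0.08) and Mki67 (−0.97 ± 0.12) did not pass.

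Extracellular matrix genes had 15 of 24 lower and 1 higher (adjusted p = 1.54e-08, and adjusted p = 0.0358 with an estimated correlation), led by the collagen genes Col1a1, Col3a1 (−2.19 ± 0.08) and Col4a1 (−2.03 ± 0.10). Other probe sets of Col1a1 and Col4a1 stood at −0.71 and −0.58 and were not called. Peritubular myoid genes had 4 of 12 lower and 1 higher (camera direction down, adjusted p = 0.0104, and adjusted p = 0.128 with an estimated correlation). Actg2, enteric smooth muscle actin, rose by 3.29 ± 0.13, from 138 ± 14.9 to 1411 ± 41.0, while Tagln fell by 1.65 ± 0.14 and desmin, Des, fell by 1.58 ± 0.30. General Sertoli cell genes had 2 of 21 lower (adjusted p = 0.0122, and adjusted p = 0.0932 with an estimated correlation), with Cst12 at −1.21 ± 0.07 and the Kit ligand Kitl at −1.03 ± 0.13, while Sox9 (−0.95 ± 0.16) did not pass. Immature Sertoli cell genes had 2 of 13 lower (adjusted p = 0.0488, and adjusted p = 0.0950 with an estimated correlation), with Bex2 at −1.15 ± 0.11 and Ccn2 at −1.03 ± 0.10, while Inha (−0.85 ± 0.08) did not pass. Adult Leydig cell genes had 3 of 11 higher and 2 lower (adjusted p = 0.144), with Ptgds at 2.83 ± 0.18, the estrogen sulfotransferase Sult1e1 at 2.81 ± 0.43 and Bhmt at 2.01 ± 0.20. Steroidogenic genes had 2 of 10 higher, Cyp17a1 and Hsd17b3, and 1 lower, Hsd3b1 at −1.03 ± 0.13 (adjusted p = 0.278).

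Among the lists that did not pass, X-linked genes had 60 of 559 higher and 101 lower (adjusted p = 0.0776), imprinted genes 1 of 15 higher and 4 lower (0.211), and retinoid genes 5 of 18 lower (0.0628). Undifferentiated spermatogonia had 1 of 23 higher and 3 lower (0.224), meiotic prophase 2 of 34 higher and 5 lower (0.241), pachytene 4 of 31 higher (0.108), and cilium and flagellum 3 of 21 higher (0.115). Cholesterol synthesis genes had 1 of 14 higher and 1 lower (0.289), macrophage and leukocyte genes 1 of 19 lower (0.309), and adipose and skeletal muscle genes 1 of 12 higher (0.148). The piRNA (0.392), endothelial (0.312), erythroid (0.283) and epididymal (0.311) lists had no member past the test. In all, 1397 genes rose and 1195 fell, so 53.9% of those called were higher. The median difference of all genes was −0.20 here, and with each array set to a common median it was −0.08, with 1582 genes higher and 819 lower (65.9% higher), so falls near 1 rest on the scaling: the calls of Hsd3b1 (−0.91), Ccn2 (−0.91) and Kitl (−0.91) ended under it. Quantile normalization ended these 3 and the calls of Mcm2 (−0.98), Stra8 (−0.97), Bex2 (−0.96) and Aldoa (0.93), which left no called member in the cell cycle list.

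Without day 20 replicate 2 the calls of Kit (−0.87) and Kitl (−0.93) ended, without day 35 replicate 1 that of Kit (−0.23), and without day 35 replicate 2 those of Kitl (−0.77), Hsd3b1 (−0.74) and Bex2 (−0.97). A pseudocount at the 40th percentile gave 683 genes lower. Averaging all probe sets gave 621, and ended the calls of Nsd3 (−0.45), Map3k2 (−0.94), Antxr1 (−0.78), Des (−0.22), Pgk1 (−0.49), Aldoa (0.98), Kitl (−0.80) and Kit (−0.31). A pseudocount at the 40th percentile ended those of Kit (−0.80) and Kitl (−0.99), and the floor those of Kit (−0.49) and Fam50a (−0.75). The call of Kit also ended, at an unchanged −1.14, in a fit on the compared days alone and at an adjusted p under 0.01. Blvrb stood at −1.46 and Kit at −2.05 without day 35 replicate 2. Averaged probe sets kept the calls of Col1a1 (−1.89), Mtcp1 (−1.03), Tssk3 (2.60) and Col4a1 (−1.30) at values moved over 1.5 times, and the floor those of Nsd3 (−1.70), Map3k2 (−1.25), Antxr1 (−1.37) and Sult1e1. Sox9 was called with a pseudocount at the 5th percentile (−1.01), with the floor (−1.02) and without day 20 replicate 2 (−1.17). Mki67 was called with the floor and without day 35 replicate 1 (−1.08), Slc2a1 without day 35 replicate 1 (−1.04) and Gmnn without day 35 replicate 2 (−1.05). Other probe sets pointed the other way and were not called for Tssk3 (−0.21), Nsd3 (0.57 and 0.60), Map3k2 (0.49), Antxr1 (0.71), Kit (0.53), Kitl (0.47), Des (1.15) and Pgk1 (0.57).

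Day 35 was set against day 0 for the whole course. Smcp, a protein of the mitochondrial capsule of sperm, rose by 9.79 ± 0.36, from 0.498 ± 0.257 to 7363 ± 298. Tnp2 (9.74 ± 0.29), Prm2 (9.36 ± 0.32), Cypt12 (9.18 ± 0.26), Hspb9 (9.12 ± 0.29), Hils1 (9.11 ± 0.24), Oaz3 (9.08 ± 0.39) and Fhl4 (9.07 ± 0.28) followed. The day 0 means of all but Prm2 among these 8 lay under the added constant, so the sizes and their order rest on it: with a pseudocount at the 40th percentile Smcp stood at 8.38, Tnp2 at 8.44 and Prm2 at 8.48. Odf1 rose by 8.72 ± 0.33, Tnp1 by 8.66 ± 0.28, Prm1 by 8.04 ± 0.42, Acrv1 by 7.07 ± 0.36, Piwil1 by 5.29 ± 0.17, Hspa2 by 4.89 ± 0.14 and Sycp3 by 2.97 ± 0.10. Col1a1 fell by 6.69 ± 0.16, from 2885 ± 239 to 20.7 ± 7.77, while another of its probe sets stood at −1.87. Itm2a fell by 6.59 ± 0.24, Dlk1 fell by 6.40 ± 0.37, Mfap4 fell by 6.11 ± 0.21, Plagl1 fell by 6.05 ± 0.11, Agtr2 fell by 5.99 ± 0.33, the activin subunit Inhba fell by 5.82 ± 0.23 and Lgals7 fell by 5.82 ± 0.33. Igf2 fell by 4.18 ± 0.15, Mki67 fell by 3.14 ± 0.12, Hsd17b3 fell by 1.84 ± 0.13 and Cyp26b1 fell by 1.76 ± 0.16, and Stra8 rose by 1.05 ± 0.11. Star (−0.94 ± 0.19), Kit (−0.81 ± 0.36), Dnmt3l (−0.44 ± 0.36), Cyp17a1 (0.42 ± 0.12) and Hba-a1 (0.52 ± 0.52) did not pass.

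All 34 round spermatid genes rose (adjusted p = 9.39e-17), with Crisp2 at 8.88 ± 0.28, Tssk2 at 8.72 ± 0.28 and Gk2 at 8.69 ± 0.16. Elongating spermatid genes had 31 of 33 higher (adjusted p = 2.12e-15), led by Smcp, Tnp2 and Prm2. Pachytene genes had 26 of 31 higher and 1 lower (adjusted p = 2.46e-11), with Meig1 rising from 10.7 ± 0.924 to 6670 ± 85.6 in intensity, Ybx2 at 7.19 ± 0.12 and Adam2 at 6.92 ± 0.34. Meiotic prophase genes had 23 of 34 higher and 2 lower (adjusted p = 3.19e-07), with Syce1 at 4.91 ± 0.10, Spo11 at 4.44 ± 0.20 and Terb1 at 4.01 ± 0.16. Cilium and flagellum genes had 20 of 21 higher (adjusted p = 2.67e-10), with Rsph1 at 6.19 ± 0.12, Spag16 at 6.05 ± 0.24 and Tekt1 at 5.86 ± 0.29. The germ cell isoforms of energy metabolism had 16 of 17 higher (adjusted p = 6.15e-11), with Pgk2 at 8.70 ± 0.33, Ldhal6b at 8.66 ± 0.15 and Ldhc at 7.61 ± 0.22. These 6 lists passed with an estimated correlation (the highest adjusted p was 0.0184). The somatic counterparts had 11 of 14 lower and 1 higher (adjusted p = 1.44e-04, and adjusted p = 0.0803 with an estimated correlation), with Pgk1 at −2.81 ± 0.12, Slc25a4 at −2.37 ± 0.12 and Pdha1, on the X chromosome, at −2.32 ± 0.15. The piRNA pathway list had 12 of 17 higher and 1 lower (adjusted p = 3.13e-05, and adjusted p = 0.0831 with an estimated correlation), with Ddx25 at 3.80 ± 0.13, Tdrd12 at 3.21 ± 0.14 and Pld6 at 3.19 ± 0.15.

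Extracellular matrix genes had 23 of 24 lower (adjusted p = 5.95e-12, and adjusted p = 0.0152 with an estimated correlation), with Col1a1, Mfap4 and Col5a2 (−5.36 ± 0.22) first. Immature Sertoli cell genes had 10 of 13 lower and 1 higher (adjusted p = 3.52e-04, and adjusted p = 0.0131 with an estimated correlation), with Amh at −5.36 ± 0.28, Hsd17b1 at −5.32 ± 0.33 and Bex2 at −3.79 ± 0.11. Imprinted genes had 11 of 15 lower (adjusted p = 5.40e-05, and adjusted p = 0.0950 with an estimated correlation), with Dlk1, Plagl1 and Mest (−4.95 ± 0.18) first. X-linked genes had 273 of 559 lower, 274 adjusted over the list alone, and 109 higher (adjusted p = 9.36e-05, and adjusted p = 0.0116 with an estimated correlation), and their largest changes were the rises of Tsga8 (8.13 ± 0.33), H2ap (7.82 ± 0.44) and Akap4 (7.74 ± 0.37). Cell cycle genes had 11 of 26 lower and 4 higher (adjusted p = 0.0182, and adjusted p = 0.227 with an estimated correlation), with Cdt1 at −3.21 ± 0.10, Mki67 and Mcm4 (−2.73 ± 0.11) first. Endothelial genes had 10 of 14 lower (adjusted p = 0.0441, and adjusted p = 0.152 with an estimated correlation), with Eng at −3.02 ± 0.31, Vwf at −2.72 ± 0.35 and Esam at −2.18 ± 0.24. Macrophage and leukocyte genes had 7 of 19 higher (adjusted p = 0.0440, and adjusted p = 0.329 with an estimated correlation), with H2-Ab1 at 1.68 ± 0.40, Cx3cr1 at 1.55 ± 0.26 and the mannose receptor Mrc1 at 1.38 ± 0.13.

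The lists that did not pass over the whole course were general Sertoli cell genes, 6 of 21 higher and 12 lower (adjusted p = 0.0525), steroidogenic genes, 1 of 10 higher and 5 lower (0.0525), and peritubular myoid genes, 1 of 12 higher and 7 lower (0.0525). Adult Leydig cell genes had 5 of 11 higher and 5 lower (0.735), differentiating spermatogonia 6 of 15 higher and 2 lower (0.316), undifferentiated spermatogonia 2 of 23 higher and 11 lower (0.141), and retinoid genes 3 of 18 higher and 6 lower (0.469). Cholesterol synthesis genes had 1 of 14 higher and 5 lower (0.0953), epididymal genes 4 of 6 higher (0.311), adipose and skeletal muscle genes 4 of 12 higher and 2 lower (0.556), and erythroid genes 1 of 5 higher and 1 lower (0.911). In all, 4484 genes rose and 4536 fell, against 4807 and 4166 with each array set to a common median and 4347 and 4291 under quantile normalization, and this comparison crosses the same step in the lowest values, from 1.61 to 8.09 in the control probe sets. A pseudocount at the 40th percentile ended the call of Stra8 (0.91). Without day 35 replicate 1 that call (0.96) also ended. Star was called without day 35 replicate 1 (−1.32) and with averaged probe sets (−1.02), and another of its probe sets stood at −1.20 and was called. Kit was called without day 35 replicate 2 (−1.72) and with a pseudocount at the 5th percentile (−1.07), but stood at 0.10 without day 35 replicate 1 and at 0.04 with averaged probe sets, so its direction is not settled. Averaged probe sets kept the calls of Oaz3 (3.83), Col1a1 (−4.28), Dlk1 (−3.98), Plagl1 (−3.62), Inhba (−2.36), Igf2 (−2.36), Cdt1 (−1.77), Spag16 (2.34) and H2ap (4.09) at values moved over 1.5 times, and the floor did so for Vwf (−1.45) and Spag16. Leaving out probe sets prone to cross-hybridization put Plagl1 at −3.87.

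Over the 5 comparisons, 64 of 130 list tests passed, 30 upward and 34 downward, and 37 of them also passed with an estimated correlation. The counts of members were identical over all genes and adjusted over the list alone in 118 of the 130 tests, and the other 12 are given above.

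Steps between neighbouring days differed widely in size. From day 14 to day 18, 2239 genes rose and 598 fell, and from day 20 to day 30, 1616 rose and 1106 fell. From day 10 to day 14, 657 rose and 105 fell, and from day 18 to day 20, 441 rose and 135 fell. Between days 3 and 6, 221 rose and 64 fell, between days 8 and 10, 105 and 60, between days 0 and 3, 27 and 67, and between days 6 and 8, 32 and 9. Between days 30 and 35, 102 rose and 219 fell. The steps have unequal lengths, and that from day 14 to day 18 crosses the change in the lowest values and in the Actb difference between 3' and 5' probe sets, from 0.655 and 0.812 to 1.07 and 1.15. The Gapdh difference went from −0.415 and −0.394 to −0.385 and −0.314. The total of 94 genes between days 0 and 3 was 52 under quantile normalization, 41 without day 0 replicate 1, 60 without day 0 replicate 2, and 59 without either array of day 3. That of 165 between days 8 and 10 was 100 without day 10 replicate 1, that of 576 between days 18 and 20 was 379 without day 18 replicate 1, and that of 321 between days 30 and 35 was 520 without day 30 replicate 1.

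**Figure D4:**
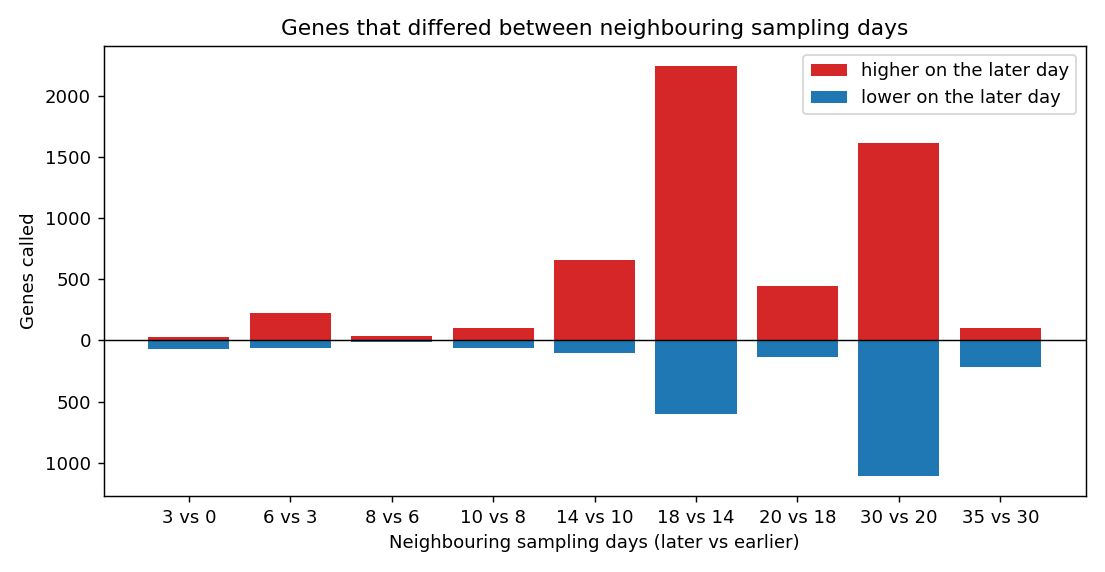
Number of genes higher and lower at each step between neighbouring days (limma, adjusted p under 0.05 and at least 2-fold, 2 arrays a day). The steps from day 14 to day 18 and from day 20 to day 30 hold the most genes, 2837 and 2722.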

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

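Of the tests below, those of the scaling factor, the share of genes at or under the control level, the gain in intensity and the X-linked median were chosen after the related result was seen, and the set of control probe sets was settled after its outcomes were seen. The tests of the day 0 label, of dilution and of normalization were written before their results.

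The lowest intensities were higher on the 8 arrays of days 18 to 35 than on the 12 arrays of days 0 to 14, a signal in control probe sets that no comparison uses. The 27 bacterial probe sets outside the hybridization controls had a median of 8.09 on the later arrays against 1.61 on the earlier ones, and those for the Bs-thr transcript reached 44.1 on 1 later array against at most 7.78 on any earlier one. A larger scaling factor that made up for weaker signal of the sample alone would raise the hybridization controls as well. Their ratio, however, was 1.01 against 5.03 for the bacterial probe sets. On arrays dimmer as a whole, a larger factor would only restore these controls, so the ratio cannot decide on that case. An additive rise in low values as the source of most genes higher on day 20 than on day 14 is argued against by the 73.7% of them that gained more intensity than the 95th percentile of these controls, while 16.5% had a day 20 mean at or under that level, or 3.44% without the Bs-thr probe sets, so a rise in low values may account for part of them and this part cannot be told apart from a change with age. No label says whether the Bs transcripts were added, and days and sets of arrays are confounded. A change of batch and a biological change therefore both stay open, as does RNA quality, which was not tested. The Actb difference between 3' and 5' probe sets was also higher on days 18 to 30 (1.07 to 1.18) than on days 0 to 14 (0.655 to 0.978). On day 35 it was lower again (0.878 and 0.953) while the control medians stayed at 9.19 and 7.95. Among the arrays of days 0 to 14, only day 8 replicate 2 (0.978) exceeded these day 35 values. The next highest was 0.812 (day 14 replicate 2). The same difference for Gapdh ran from −0.418 to −0.175 on days 0 to 14. The Gapdh values of day 18 (−0.385 and −0.314) and day 20 (−0.357 and −0.215) lay inside that range. Those of day 30 (0.053 and −0.065) lay above it.

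The array titled day 18 replicate 2 names day 0 in its source label. Its correlation across genes was 0.773 with the mean of the day 0 arrays and 0.969 with day 18 replicate 1, a difference of 0.196 against at most 0.0348 between the replicate correlations of other days. A day 0 sample is therefore argued against by its values, and no biological explanation was tested. With the mean of the day 20 arrays the correlation was 0.958, so the values do not tell day 18, the day of its title, apart from day 20. Correlations across genes do not count genes as independent replicates.

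X-linked genes were lower on day 20 than on day 14 more often than autosomal ones. Among genes that rose by day 8, the 49 X-linked ones had a median change of −1.10 and the 489 autosomal ones −0.47. The difference was −0.63 (two-sided permutation of chromosome labels over genes, p = 4.8e-04). That test took genes as independent units, so its p-value does not measure spread between samples. The comparison cannot decide on dilution of the cell types present before meiosis. Genes that rose by day 8 are not confined to those cell types, as they included 16 of 34 meiotic prophase genes. Under quantile normalization the difference in medians between all X-linked and autosomal genes was −0.64. Scaling of whole arrays moves both medians much alike, so this difference could hardly vanish. No conclusion on normalization between arrays is drawn from it. The X-linked median of −0.72 was the lowest of 20 chromosomes, and also the lowest among genes that rose by day 8, where some autosomes held few genes (9 at the fewest). A chromosome-wide fall of X-linked transcripts in meiotic cells may account for it, as a hypothesis found and tested on the same arrays, which also cross the step in low values.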

How the results depend on the processing

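The floor at the pooled median was chosen after seeing the data, and all other alternatives were planned. Of 350 gene results, 325 were called, and 260 of these kept their call in each of the 35 alternatives in which the gene was tested. A few genes were not tested in every alternative, and dropping the minimum difference cannot end a call. Many of these genes were picked for large changes on the same arrays, so this share does not describe called genes in general. Kit on day 35 against day 0, which did not pass at −0.81, stood at 0.0401 with the mean of all probe sets, and the cause was not tested. Counts moved over 1.5 times as follows. Quantile normalization gave 52 genes between days 0 and 3 (94). A pseudocount at the 40th percentile gave 283 lower on day 8 than day 0 (455), 247 lower on day 14 than day 8 (410) and 683 lower on day 35 than day 20 (1195), and the mean of all probe sets gave 621 for the last. Testing every probe set, which adds tests, gave 22399 over the time course, 847, 2192 and 7012 higher on day 8 than 0, 35 than 20 and 35 than 0, and 751, 637, 3822, 2229 and 8619 lower in the 5 comparisons in order. Dropping the minimum difference gave 2070 and 2227 higher and 1496 and 1903 lower on day 8 than 0 and 14 than 8, and 4857 and 5193 lower on day 20 than 14 and 35 than 20. An adjusted p under 0.01 gave 291 lower on day 8 than day 0, and the floor 1782 higher on day 20 than day 14. Of 64 list tests called, 37 held with an estimated correlation, and fry called 108, among them the general Sertoli cell list on day 14 against day 8 upward (adjusted p = 7.33e-04), where camera pointed down (adjusted p = 0.347). Quantile normalization called 68 and a common median 67. List levels turned in sign for members above the median level: undifferentiated spermatogonia on day 14 (0.46, from −0.20), immature Sertoli cells on days 8 (0.39, from −0.28) and 10 (0.31, from −0.34), and macrophages on day 3 (0.0672, from −0.22). Under quantile normalization the adipose and skeletal muscle list on day 30 stood at −0.0379 (from 0.38). The cause of these was not tested.

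Leaving out 1 array, with the lone array of that day assumed to vary like the others, gave 12572 to 12909 genes over the time course. Genes higher ran from 465 to 556 (day 8 against 0), 784 to 925 (14 against 8), 2613 to 3033 (20 against 14), 1325 to 1426 (35 against 20) and 4151 to 4507 (35 against 0), and genes lower from 294 (without day 0 replicate 2) to 477, 306 to 424, 1685 to 1939, 1186 to 1470 and 4447 to 4544. The 9 neighbouring steps ran in order from 41 (without day 0 replicate 1) to 105, 218 to 301, 31 to 46, 100 (without day 10 replicate 1) to 183, 632 to 783, 2363 to 2895, 379 (without day 18 replicate 1) to 623, 2595 to 3169 and 271 to 520 (without day 30 replicate 1). Kit on day 35 against day 0 ran from −1.72 to 0.10. Replicate numbers do not pair arrays: deviations of replicate 1 correlated between −0.0249 and 0.0561 over 45 pairs of days, and with replicate as a block 12756 genes passed over the time course. Of 204 other probe sets of named genes, 29 pointed the other way and 2 were called so, those of Igf2 (1.27) and Ndn (1.15).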

Other observations

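The groups below hold genes that share the stem of their symbol and need not be related. They were formed after seeing the data, so all their tests were chosen then. Spata abbreviates spermatogenesis associated, so a rise of that group is partly built into its name. Among 264 such groups, tested with camera in 5 comparisons, 76 of 1320 tests passed and 8 of these also passed with an estimated correlation. The Cfap genes of cilia and flagella had 15 of 24 members higher on day 14 than on day 8 (median 1.27) and 20 of 24 higher on day 20 than on day 14 (median 2.37). Over the whole course 22 of the 24 Cfap genes rose (median 4.34, and 4.33 under quantile normalization), with none lower in these 3 comparisons. The Spata genes had 13 of 22 members higher on day 35 than on day 20 (median 1.91) and 18 of 22 higher than on day 0 (median 5.14). The Ccdc genes had 22 of 115 members higher and none lower on day 14 than on day 8 (median 0.23), 45 higher and 1 lower on day 20 than on day 14 (median 0.56), and 61 higher and 18 lower on day 35 than on day 0 (median 1.29). The 8 tests each had an adjusted p = 0.0277 with an estimated correlation, and their medians kept their sign under quantile normalization and a common median.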
